A study of Mus musculus with 2 samples.

How the data were processed

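The measurement was droplet single-cell RNA sequencing of mouse cochlea at 20 days of age, in 1 group of 2 libraries. Per the labels' protocols, cochleae of 5 to 8 C57BL/6 mice were taken, cells were separated with trypsin, and libraries were read on an Illumina HiSeq. The deposited values were whole-number counts of UMIs per gene and barcode, made by the authors with Cell Ranger 2.1.0 on the mouse genome build mm10, per the submitters' processing notes. The barcodes had been selected before deposit, 1610 in library 1 and 720 in library 2, over 27998 genes. How barcodes were selected is not given in the sources used here, and empty droplets were not analysed here. The counts summed to 20212520 and 7094752 UMIs. Of the gene symbols, 121 stood on several identifiers, and genes were held apart by identifier.

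Cells were kept with at least 300 genes and at most 20% mitochondrial UMIs. This removed 279 barcodes in library 1 (275 for few genes and 4 for mitochondrial UMIs) and 76 in library 2 (60 and 16). Scrublet, run per library with an expected rate of 2%, marked 2 doublets in library 1 (0.150%) and 5 in library 2 (0.776%), which were removed, and 1968 cells remained. A rate of 6% also marked 2 and 5. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes and the fixed markers, 2027 in all, entered 30 principal components, a graph of 15 neighbours and Leiden clustering at resolution 1.0 with seed 0 (scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Python 3.11.15). So that classes were not tested on the genes that defined them, clustering used the markers and the genes whose identifier had an odd checksum, while 14172 genes, among them every gene of the lists, were held out. Cluster-defining genes are given only to identify clusters.

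Before the data were examined, 213 markers in 27 lists, 22 gene lists with 556 genes, the tests, the alternatives and the rule for named genes were fixed. A cluster was called X-like when at least 3 markers of a list, and at least 40% of it, were higher than in the other cells by a log2 fold of 1 (on CPM plus 10) and seen in 10% of its cells, with a margin of 20 percentage points over the next list and with a leading gene seen in 25% of its cells. Clusters of the same name were merged, which joined 4 clusters as erythroid cell-like and 2 as hair cell-like, and the others kept their numbers. The thresholds for naming and the Scrublet rate of 2% were set after a first clustering with a rate of 6% had been seen. Droplets can also hold free RNA, which would add UMIs of abundant genes to cells that do not express them, and no correction was made for it.

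Raw counts were summed per library and class. Classes with at least 10 cells in each library, 11 classes and 22 sums, entered 1 fit in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with TMM factors, filterByExpr with a minimum count of 10 (10790 genes), robust quasi-likelihood fitting (common dispersion 0.0222, prior degrees of freedom 83.9, residual degrees of freedom 10) and the library as a replicate block, since classes of 1 library came from the same cells in suspension. Each class was compared with the unweighted mean of the other classes, and cochlear fibrocyte-like with connective tissue fibroblast-like cells, the only planned pair of related classes with enough cells. The 5581 held-out genes were tested, with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. A log2 fold change is therefore a mean of log differences, not the log of a ratio of mean CPM, and its SE was derived from the fold change and the F statistic. CPM values of the fitted classes are means ± SD over 2 libraries, on library sizes scaled by the TMM factors. In the second fit below these factors lay between 0.814 and 1.96, except in erythroid cell-like cells (0.236 and 0.185), whose CPM values are raised accordingly. CPM values of classes from a single library were not scaled. The sums ranged from 60075 counts (cluster 8 in library 2) to 4771293 (erythroid cell-like in library 1), and hair cell-like cells had 745343 and 36019. The precision of rare classes is limited by these depths. Shares of cells carry exact binomial 95% intervals and single-library values exact Poisson 95% intervals, which cover counting error only. A count of 0 was given a limit of 3 counts.

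The lists were 8 groups of deafness genes (hair bundle and mechanotransduction, hair cell synapse, channel or motor, gap and tight junction, ion and metabolite transport, extracellular matrix and tectorial membrane, transcription factor, signalling and receptor, and mitochondria, translation or other), genes near adult hearing difficulty association signals, connexins and pannexins, potassium and chloride handling, matrix, complement, cytokines and chemokines, growth and neurotrophic factors, glutamate receptors, transporters and synaptic vesicle, immediate early and heat shock, antioxidant and glutathione, oxidative phosphorylation, glycolysis, cell cycle, and antigen presentation. Of their genes 548 were found and 417 tested. Of 174 deafness genes 167 were found and 117 tested. Lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01 and with an estimated one, adjusted over all lists and contrasts. Counts of a list adjusted over the list alone are given where they differ from those over all tested genes. A list's median, mean and test differed in sign in 62 of 264 tests, none of them past the threshold, and in the second fit below in 22 of 88, of which 1 passed.

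Genes were named by a fixed rule: per class up to 6 deafness genes, 6 genes of other lists and 4 other held-out genes with the largest log2 fold change among those past the threshold and higher in both libraries, and for the pair of classes 6 list genes in each direction. Gene models without a symbol of their own and ribosomal protein genes were left out of the last group, and 16 genes were fixed whatever their values. Some genes named by this rule, 1 of the 16 among them, are not reported here. A library difference within a small tolerance of 0 was given no direction, a tolerance added after a gene with 0 counts in 1 library had been named by rounding. Identifiers were matched to GENCODE release M21 (GRCm38, the same assembly as mm10), and 218 of 218 were found. Coordinates are 1-based.

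Alternatives fixed beforehand were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no count filter, no replicate block, each library left out, resolutions of 0.5 and 2.0, no doublet removal, clustering on all variable genes, at least 20 cells, and for shares at least 500 genes with at most 10% mitochondrial UMIs. Added after seeing the data were a second fit with at least 3 cells per class and library (15 classes, 6068 genes), haemoglobin genes left out, the erythroid class left out, genes centred within each library before clustering, cells over 5% haemoglobin left out, the Scrublet rate of 6%, and fibrocyte-like cells with more UMIs of stria marginal than of fibrocyte markers left out. Clusters of other clusterings were matched to the main ones at a Jaccard index of at least 0.5. The test was checked on simulated counts in which 200 genes were changed. For cochlear fibrocyte-like cells, over 5004 genes, it recovered 63.7% of 91 genes changed 2-fold and 100% of 96 changed 4-fold, with 5 false calls. The simulated classes shared 1 mean profile and 1 common dispersion (0.0222), without a difference between libraries. The real classes differ widely, so these values do not give the error rates of the test on the real data.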

Results

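The cochlea, the spiral organ of hearing, was profiled by droplet single-cell RNA sequencing in C57BL/6 mice at 20 days of age, after hearing onset. The stated purpose of the series was to survey which genes the young cochlea expresses. The samples form 1 group of 2 libraries, and the labels give 5 to 8 mice with no statement that the libraries came from separate pools of animals. The p-values below therefore rest on how far class differences varied between these libraries, a variation that may be technical. It was estimated after the replicate block had removed the mean difference between the libraries, and it drew on all fitted classes and genes. Library 1 held 1610 barcodes and 20212520 UMIs (unique molecular identifiers, 1 per captured transcript), and library 2 held 720 barcodes and 7094752 UMIs. After filtering, 1329 cells with a median of 10601 UMIs and 2414 genes remained in library 1, and 639 cells with a median of 6119 UMIs and 2173 genes in library 2. Haemoglobin genes took 25.4% of all UMIs in library 1 and 12.6% in library 2.

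Erythroid cell-like cells, red cell precursors named from haemoglobin and other fixed markers, made up 30.7% of library 1 (408 cells, exact binomial 95% interval 28.2% to 33.3%) and 6.10% of library 2 (39 cells, 4.37% to 8.25%). These shares depend on the minimum of 300 genes, and no lower minimum was tried. The 275 and 60 barcodes removed for few genes held 95.1% and 96.0% haemoglobin UMIs. Their ratio of the haemoglobin genes Hbb-bs to Hba-a1 was 1.78 and 1.29, against 1.76 and 1.28 in erythroid cell-like cells. Connective tissue fibroblast-like cells took the reverse order, with 11.8% in library 1 (157 cells) and 26.4% in library 2 (169 cells). They were named from 4 of 9 fibroblast markers (Col3a1, Pdgfra, Dcn and Apod). Their 10 leading genes held 1 fibroblast marker (Dcn) and 1 stria basal cell marker (Cldn11). Cochlear fibrocyte-like cells made up 3.46% and 5.32%. Cochlear fibrocytes line the lateral wall and carry potassium ions back towards the endolymph. The class was named from 3 of 7 fibrocyte markers (Otos, Kcnk2 and Car3). Other fibrocyte markers were higher in unnamed clusters, so the class need not hold all fibrocytes. Hair cell-like cells, the sensory receptors of hearing, made up 3.61% of library 1 (48 cells) and 0.626% of library 2 (4 cells). Macrophage-like cells made up 1.58% and 2.50%, and non-sensory cochlear epithelium-like cells 1.20% and 2.19%. Other classes came almost entirely from a single library and may reflect that library. B lineage-like cells numbered 70 and 1, organ of Corti supporting cell-like cells 27 and 0, spiral ganglion neuron-like cells 6 and 0, and stria intermediate cell-like cells 2 and 19. The 0 of 639 supporting cell-like cells allows a share of up to 0.576% in library 2 (exact binomial 95% interval). Clusters that met no naming rule are given by number with their leading genes. Cluster 3 was led by Sptssb, Tnfaip6 and Cebpb, cluster 4 by Kcnk3, Nov and Ccnd2, cluster 5 by Hal, Tnc and Npy, cluster 6 by Lox, Rarres1 and Coch, and cluster 8 by Mgp, Fst and Col2a1. Cluster 6 carried 4 of 9 endothelial markers, and cluster 8 carried 4 of 9 fibroblast and 4 of 9 osteoblast markers. Clusters 3, 4 and 5 carried at most 2 markers of any list. In cluster 4 these were 2 of 7 fibrocyte markers (Otor and Tbx18) and 2 endothelial markers. Otor also stood among the 10 leading genes of cluster 6. Cluster 5 carried 2 of 5 stria basal cell markers (Nrp2 and Nr2f2) and 2 tympanic border or mesothelial cell markers. It matched a stria basal cell-like cluster at a resolution of 2.0 (Jaccard index 0.992) and without doublet removal (0.956). Cluster 11 (Ucma, Frzb, Epyc) carried 6 of 12 non-sensory epithelial markers and 2 chondrocyte markers. None of the former stood among its 10 leading genes, against 2 markers of other classes. Cluster 15 (Fibin, Otol1, Lfng) carried 5 of 8 supporting cell and 5 of 12 non-sensory epithelial markers, and cluster 16 (Fabp7, Fzd9, Epyc) 4 of 8 and 7 of 12. Cluster 14 (Ngp, Camp, S100a8) carried 10 of 10 neutrophil lineage markers and 6 monocyte markers. At a resolution of 2.0 and on all variable genes it matched a monocyte-like cluster (Jaccard index 0.587 and 0.544). In both settings a separate neutrophil lineage-like cluster held 24 and 2 cells. Cluster 3 held 2.11% of library 1 and 19.2% of library 2, and cluster 6 held 3.84% and 11.7%. The intervals of the libraries overlapped for clusters 4 and 5 and for fibrocyte-like, macrophage-like, non-sensory epithelium-like and spiral ganglion neuron-like cells. They did not overlap for any other class, so the shares describe single libraries.

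**Figure D1:**
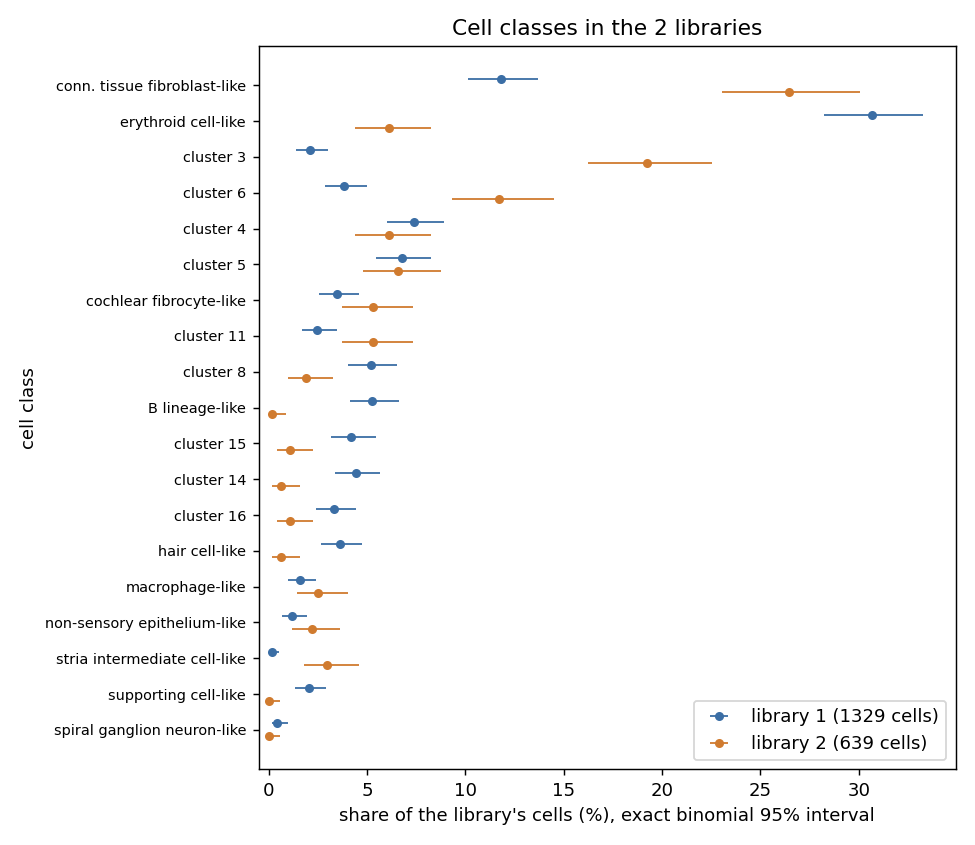
Share of each library's cells (%, x axis) in the 19 cell classes and unnamed clusters (y axis), as points with exact binomial 95% intervals for library 1 (1329 cells) and library 2 (639 cells). Erythroid cell-like cells made up 30.7% of library 1 and 6.10% of library 2, and cluster 3 made up 2.11% and 19.2%.

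Expression within a class was compared between the libraries. Over 11809 genes, the log2 CPM of connective tissue fibroblast-like cells had a Spearman correlation of 0.945 between libraries, against 0.899 for the best matching other class. The correlations were 0.914 for cochlear fibrocyte-like cells (0.819 for the best other class), 0.967 for cluster 4 (0.952), 0.777 for macrophage-like cells (0.602), 0.777 for erythroid cell-like cells (0.634) and 0.726 for hair cell-like cells (0.680). Clusters 8, 14, 15 and 16 matched another class of the other library better than themselves, with 0.766 against 0.887, 0.611 against 0.684, 0.750 against 0.838 and 0.845 against 0.848. Their sums in library 2 held only 60075, 27915, 45645 and 103982 counts, and low depth as a reason was not tested. Hair cell-like cells, with 36019, still matched themselves best. The best other class was sought only in library 2, for the class in library 1. All these values are correlations across genes, which are not independent replicates.

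The 16 genes fixed for reporting whatever their values include the main genes of hereditary deafness. Values of clusters 15 and 16 and of hair cell-like cells come from the second fit described below, and the others from the first. The fits differ in their scaling factors and in the classes compared with. Library 2 held 7 cells of cluster 15, 7 of cluster 16 and 4 hair cell-like cells. Gjb2 (connexin 26, ENSMUSG00000046352, chromosome 14, 57098600 to 57104702, minus strand, GRCm38) and Gjb6 (connexin 30, ENSMUSG00000040055, chromosome 14, 57123303 to 57133611, minus strand) form the gap junctions of the cochlea. Gjb2 reached 2982 ± 368 CPM in cochlear fibrocyte-like cells, 1088 ± 595 in cluster 11 and 1336 ± 371 in cluster 15 (mean ± SD, n = 2), and Gjb6 reached 1018 ± 127, 739 ± 347 and 1207 ± 147. In connective tissue fibroblast-like cells Gjb2 stood at 33.8 ± 18.8 CPM. Coch (cochlin, a secreted protein mutated in the deafness DFNA9, chromosome 12, 51593341 to 51605771, plus strand) was highest among the tested classes in cluster 6, at 12450 ± 3371 CPM, followed by cluster 5 at 6359 ± 806, cluster 8 at 5798 ± 2087 and cluster 3 at 4460 ± 2084. Coch was also higher than in the other classes in cochlear fibrocyte-like cells (log2 fold change 0.84 ± 0.21 SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0011) and lower in connective tissue fibroblast-like cells (-3.17 ± 0.30). Pou3f4 (a transcription factor of the inner ear mesenchyme and an X-linked deafness gene, chromosome X, 110814280 to 110817207, plus strand) was higher in clusters 3, 4, 5, 6 and 8 and in both fibrocyte-like and fibroblast-like cells, with log2 fold changes from 2.12 to 2.73. It had 0 counts in both libraries of cluster 11. Atp1b1, the sodium pump subunit, reached 2008 ± 31.7 CPM in cochlear fibrocyte-like cells, 1444 ± 19.3 in cluster 11 and 1065 ± 218 in cluster 16. Kcnj10, the potassium channel Kir4.1, was higher in clusters 11 (57.0 ± 23.2 CPM, log2 fold change 4.41, on 18 and 22 counts in libraries 1 and 2) and 16 (71.2 ± 26.1, 3.83, on 48 and 10). It was also called in erythroid cell-like cells (1.89), on 7 and 3 of 4771293 and 500272 counts. In that class low TMM factors raise the scaled values. The calls in cluster 15 (4.60, on 89 and 1 counts) and in hair cell-like cells (3.46, on 41 and 1) rest on library 1. Wfs1, the Wolfram syndrome gene, was higher in cochlear fibrocyte-like cells (53.8 ± 5.85 CPM, log2 fold change 3.22 ± 0.34). Tecta, a tectorial membrane protein, had at most 5 counts in any sum and was not tested.

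**Figure D2:**
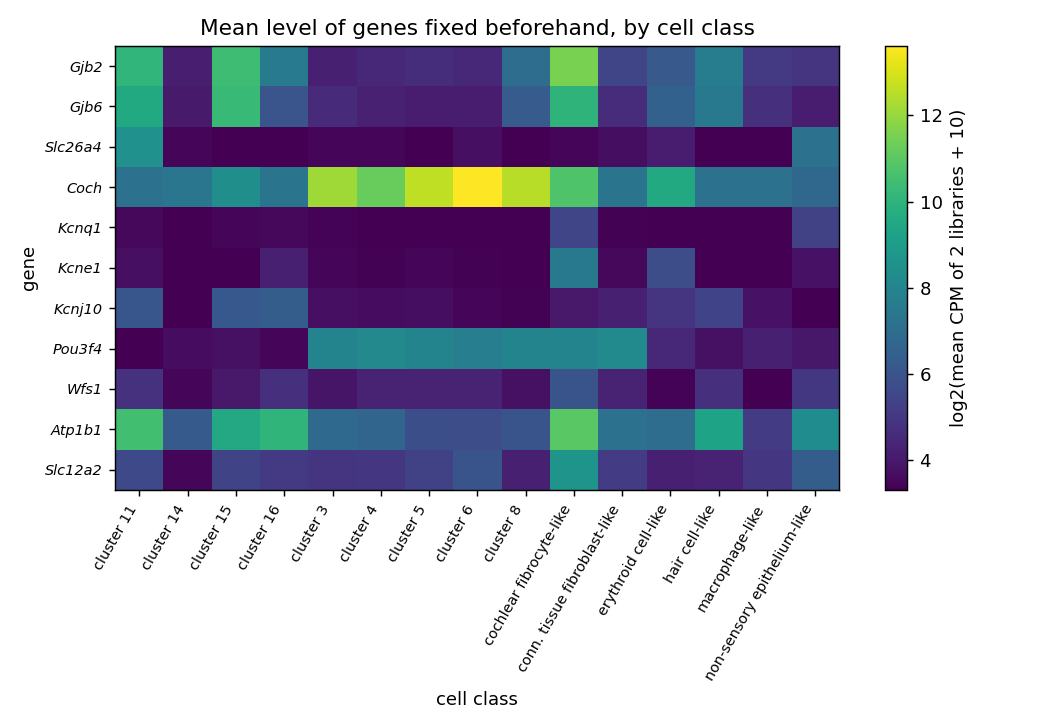
Mean level of 11 of the fixed genes (y axis) in 15 cell classes (x axis), as log2 of the mean CPM of 2 libraries plus 10 (colour scale). Gjb2 and Gjb6 stand out in cochlear fibrocyte-like cells and clusters 11 and 15, Coch in clusters 3, 4, 5, 6 and 8, and Pou3f4 in the same clusters and in fibrocyte-like and fibroblast-like cells.

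Cochlear fibrocyte-like cells were compared with the mean of the other 10 tested classes. Gjb2 was higher by a log2 fold change of 6.31 ± 0.23 (SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.3e-15) and Gjb6 by 5.45 ± 0.17 (adjusted p = 1.3e-39, same edgeR test). The differences in libraries 1 and 2 were 6.00 and 6.80 for Gjb2 and 4.94 and 5.66 for Gjb6. The sodium pump subunit Atp1b1 (4.26 ± 0.15), the potassium channel Kcnk1 (4.66 ± 0.30, with 3.31 and 4.37 in libraries 1 and 2) and Ppargc1a, a regulator of mitochondrial genes (7.01 ± 0.31, 141 ± 0.448 CPM), were higher as well. So were the collagen Col15a1 (4.92 ± 0.41, with 3.13 and 3.73), the actin regulator Eps8l2 (5.11 ± 0.32), the pigment cell transcription factor Mitf (3.96 ± 0.45, with 2.28 and 2.97), the lipid droplet protein Plin4 (8.01 ± 0.44, with 4.68 and 5.29) and the ketone body enzyme Bdh1 (6.68 ± 0.33). Differences given per library are on a log2 CPM scale with a prior count of 2, a scale other than that of the fitted values. Of the 5581 genes tested, 1049 were higher and 435 lower, 1018 of the former in both libraries. Of 117 deafness genes 40 were higher and 2 lower, and 41 were higher when adjusted over the list alone.

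Of 50 nuclear oxidative phosphorylation genes, which build the respiratory chain, 49 were higher in cochlear fibrocyte-like cells, and 50 when adjusted over the list alone (camera, adjusted p = 5.0e-35, and adjusted p = 0.0537 with an estimated correlation). Mitochondrial genes took a median of 9.33% of a cell's UMIs in this class, against 3.11% in fibroblast-like cells. With at least 500 genes and at most 10% mitochondrial UMIs its mean share of cells fell from 4.39% to 2.31%. Cells were clustered and named again in that setting (Jaccard index 0.776 among the cells kept). The fall therefore mixes cells left out with cells grouped otherwise. The list was not tested under that filter, so cell quality stays open as a source of this result. Of 19 glycolysis genes 15 were higher (adjusted p = 3.4e-11, and adjusted p = 0.0218 with an estimated correlation). Of 20 potassium and chloride handling genes 11 were higher (2.9e-06, and adjusted p = 0.0511 with an estimated correlation). Of 5 connexins and pannexins 2 were higher (0.0283, and adjusted p = 0.149 with an estimated correlation). Of 13 deafness genes of signalling and receptors 7 were higher and the list did not pass (camera with Benjamini-Hochberg adjustment over all lists and contrasts, limma, adjusted p = 0.112). Immediate early and heat shock genes, which respond to tissue dissociation, had 5 of 26 higher and 10 lower, 11 lower when adjusted over the list alone (0.0058, and adjusted p = 0.293 with an estimated correlation). In library 2, 9 of 34 cells of the class held more UMIs of the fixed stria marginal cell markers than of the fibrocyte markers, against 0 of 46 in library 1. Marginal cells of the stria vascularis secrete potassium through Kcne1 and Kcnq1 and take it up through the chloride cotransporter Slc12a2. Kcne1 had 0 counts in the class in library 1 and 190 in library 2, and Slc12a2 had 42 and 418 counts, with differences of 0.69 and 5.13. Without these 9 cells, a setting added after the values were seen, Slc12a2 fell from a log2 fold change of 3.65 to 1.252. In the same setting 1048 genes passed as higher, 36 of them deafness genes, and 49 of 50 oxidative phosphorylation, 15 of 19 glycolysis and 8 of 17 potassium and chloride handling genes were higher. With an estimated correlation the adjusted p (camera) was then 0.0459, 0.0229 and 0.0191 for these 3 lists.

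Fibrocyte-like and connective tissue fibroblast-like cells were compared directly, as 2 mesenchymal classes with different parts in the lateral wall and its surroundings. With genes centred within each library the fibroblast-like class held 151 and 0 cells, so this pair had no value there. Fibrocyte-like cells were higher in Gjb2 (log2 fold change 6.48 ± 0.50, with 6.89 and 6.03 in libraries 1 and 2, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.6e-09), Gjb6 (6.14 ± 0.34), the collagen Col11a2 (5.07 ± 0.39, with 3.97 and 4.91 per library) and Kcnk1 (4.10 ± 0.39, with 3.23 and 4.12). They were lower in Ccl11 (eotaxin-1, a chemokine for eosinophils) by -8.16 ± 0.60 (3.76 ± 2.13 against 1069 ± 282 CPM, adjusted p = 4.3e-09, same edgeR test). The glutamate receptor Grik1 and the cytokine Il33 had 0 counts in fibrocyte-like cells and were at least 19.7-fold and 15.6-fold lower there, taking 3 counts over both libraries as the floor. By the same floor Edn3, Tnc and Wnt5b were at least 3.31-fold, 2.39-fold and 2.02-fold lower. In total 722 genes were higher and 775 lower in fibrocyte-like cells, so that 48.2% of the calls were higher, against 51.0% with DESeq2 size factors. Without the 9 cells with stria marginal markers the counts were 699 and 756. Of 117 deafness genes 32 were higher and 12 lower, and 36 were higher when adjusted over the list alone. Of 50 oxidative phosphorylation genes 49 were higher (camera, adjusted p = 5.7e-29, and adjusted p = 0.109 with an estimated correlation), and of 30 matrix genes 16 were lower and 2 higher (7.8e-04, and adjusted p = 0.293 with an estimated correlation). Glycolysis genes were higher in 12 of 19 cases, 13 when adjusted over the list alone (2.5e-08, and adjusted p = 0.0891 with an estimated correlation). Potassium and chloride handling genes were higher in 11 of 20, 12 when adjusted over the list alone (camera, adjusted p = 6.5e-07, and adjusted p = 0.0555 with an estimated correlation). Of 27 cytokines and chemokines 7 were lower and 1 higher (0.0160, and adjusted p = 0.269 with an estimated correlation).

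Connective tissue fibroblast-like cells expressed matrix genes above the mean of the other classes. Ccl11 was higher by a log2 fold change of 6.11 ± 0.23 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.3e-13) and stood at 5.66 and 6.79 above the others in libraries 1 and 2. Grik1 was higher by 7.18 ± 0.54 (42.6 ± 5.13 CPM) and Il33, an alarm signal of barrier tissues, by 6.08 ± 0.55, with 2.29 and 4.24 in libraries 1 and 2. The matrix proteins vitronectin (Vtn, 5.67 ± 0.53) and nidogen 2 (Nid2, 3.91 ± 0.42) and the actin regulators Eps8 (3.76 ± 0.25, with 2.88 and 3.88) and Espn (43.7 ± 1.39 CPM) were higher too. Of the tested genes 852 were higher and 148 lower, and of 117 deafness genes 17 were higher and 8 lower, with 18 higher when adjusted over the list alone. Of 30 matrix genes 22 were higher, 24 and 1 lower when adjusted over the list alone (camera, adjusted p = 1.2e-11, and adjusted p = 0.0192 with an estimated correlation). Of 12 complement genes 5 were higher (Serping1, C1s1, C1ra, C2 and C4b, with adjusted p = 0.0220, and adjusted p = 0.269 with an estimated correlation). List members given here and below that the named-gene rule did not select were chosen after their values were seen. Of 13 glutamate receptor, transporter and synaptic vesicle genes 9 were higher (2.4e-05, and adjusted p = 0.0511 with an estimated correlation). Of 25 growth and neurotrophic factors 11 were higher and 1 lower (0.0120, and adjusted p = 0.0858 with an estimated correlation), and of 27 cytokines and chemokines 8 were higher (0.0370, and adjusted p = 0.269 with an estimated correlation). Oxidative phosphorylation genes were lower as a list (5.5e-07, and adjusted p = 0.445 with an estimated correlation), although 3 of 50 were called lower, and 1 when adjusted over the list alone.

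Clusters 3, 4, 5 and 6 depend on the clustering. With genes centred within each library none of them was matched, with Jaccard indices of 0.453, 0.337, 0.378 and 0.333. Clusters 3, 4 and 6 fell mostly into 1 cluster at a resolution of 0.5, and clusters 4 and 5 had no match when all variable genes were used. As clustered here, these clusters shared high Coch, Pou3f4 and Slc4a11, a transporter mutated in corneal dystrophy with hearing loss. Slc4a11 was higher by log2 fold changes of 3.40 ± 0.27 in cluster 3, 2.94 ± 0.22 in cluster 4, 2.60 ± 0.24 in cluster 5 and 3.27 ± 0.23 in cluster 6. Cluster 5 was led among deafness genes by tenascin C (Tnc, 4.77 ± 0.30, 99.6 ± 27.3 CPM), a matrix glycoprotein. Cluster 6 was led by Coch (3.91 ± 0.17, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.0e-37) and the basement membrane collagen Col4a3 (3.87 ± 0.37, with 3.28 and 2.47 in libraries 1 and 2). The B cell chemokine Cxcl13 was higher in cluster 5 by 4.16 ± 0.20 (328 ± 42.6 CPM), and Lox, the enzyme that cross-links collagen and elastin, in cluster 6 by 4.73 ± 0.18 (1547 ± 414 CPM). In cluster 3 pleiotrophin (Ptn), a secreted growth factor, reached 13720 ± 1101 CPM (2.78 ± 0.21, with 2.51 and 3.14), and in cluster 4 Nov, a matricellular protein, was higher by 4.23 ± 0.28 (141 ± 4.77 CPM, with 3.50 and 4.22). The counts of higher and lower genes were 492 and 70 in cluster 3, 1221 and 320 in cluster 4, 918 and 179 in cluster 5, and 916 and 181 in cluster 6. Deafness genes numbered 13 higher and 6 lower, 33 and 6, 25 and 8, and 23 and 4 of 117 in the same order. The higher ones adjusted over the list alone numbered 14, 34, 25 and 23. Without doublet removal cluster 3 had 317 higher, 35 lower and 7 higher deafness genes, and clustering on all variable genes gave it 143 lower genes. Counts of lower genes in clusters 4, 5 and 6 also moved with the processing, as given below.

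Immediate early and heat shock genes were higher in 18 of 26 cases in each of clusters 3, 4, 5 and 6 (camera, adjusted p = 7.4e-15, 1.2e-09, 8.3e-10 and 1.3e-09, and adjusted p = 0.0511 with an estimated correlation in each). Adjusted over the list alone, the count in cluster 5 was 19 higher and 1 lower and the others stayed at 18. In cluster 6 examples were the transcription factors Klf2 (2.45 ± 0.18) and Nr4a1 (2.40 ± 0.20, with 2.77 and 1.90). Of the UMIs outside haemoglobin, a scale added after the values were seen, the list took 4.05% ± 0.142 in cluster 4 and 0.773% ± 0.0216 in erythroid cell-like cells (mean ± SD, n = 2). In the latter, haemoglobin took a median of 88.6% and 92.2% of a cell's UMIs in libraries 1 and 2. Oxidative phosphorylation genes were lower in 5, 22, 10 and 12 of 50 cases in clusters 3, 4, 5 and 6, and in 7, 30, 10 and 13 when adjusted over the list alone (1.1e-14, 2.5e-16, 7.7e-14 and 7.7e-14, and adjusted p = 0.269, 0.269, 0.282 and 0.282 with an estimated correlation). Deafness transcription factors were higher in 9, 8 and 7 of 15 cases in clusters 4, 5 and 6, and in 9, 8 and 8 when adjusted over the list alone (0.0050, 0.0010 and 0.0030, and adjusted p = 0.130, 0.0945 and 0.108 with an estimated correlation). Antioxidant and glutathione genes were lower in 9 and higher in 3 of 28 cases in cluster 4, and 12 and 3 when adjusted over the list alone (7.5e-05, and adjusted p = 0.205 with an estimated correlation).

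**Figure D3:**
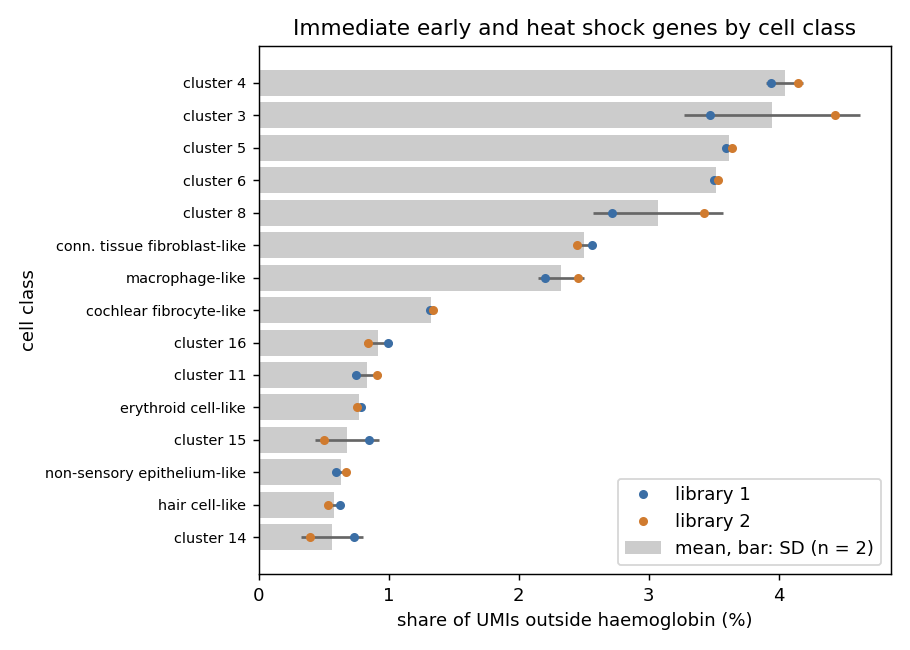
Share of the UMIs outside haemoglobin that came from the immediate early and heat shock list (%, x axis) in 15 cell classes (y axis), with library values as points, their mean as a bar and the SD over 2 libraries as a line. Clusters 3, 4, 5, 6 and 8 stand highest, with cluster 4 at 4.05%, and cluster 14 lowest at 0.564%.

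In cluster 8 follistatin (Fst), an activin antagonist, was higher by a log2 fold change of 7.54 ± 0.29 (601 ± 196 CPM, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.6e-15). The cartilage protein Chad was higher by 6.61 ± 0.36, Col9a1 of type IX collagen (chromosome 1, 24177610 to 24252684, plus strand) by 4.45 ± 0.28 and osteoglycin (Ogn) by 4.60 ± 0.21 (403 ± 5.31 CPM). Cartilage collagen Col2a1 was higher by 5.65 ± 0.35, with 5.89 and 4.70 in libraries 1 and 2. Bone collagen Col1a1 rested on library 2, with a difference of 0.84 without library 2 and 7.70 without library 1. Of the tested genes 546 were higher and 60 lower, 445 of the former in both libraries, and of 117 deafness genes 23 were higher and 3 lower, with 27 higher when adjusted over the list alone. Of 15 deafness genes of the extracellular matrix and tectorial membrane 11 were higher, 12 when adjusted over the list alone (camera, adjusted p = 7.7e-14, and adjusted p = 0.0169 with an estimated correlation). Of 30 matrix genes 24 were higher, 26 when adjusted over the list alone (2.5e-18, and adjusted p = 0.108 with an estimated correlation). Of 26 immediate early and heat shock genes 13 were higher, or 16 when adjusted over the list alone (camera, adjusted p = 7.8e-08, and adjusted p = 0.0891 with an estimated correlation), and of 5 connexins and pannexins 4 (0.0030, and adjusted p = 0.0692 with an estimated correlation). Of these, Gjb2 and Gjb6 turned from 1.41 and 1.05 to -0.49 and -0.61 with genes centred within each library, and Gjb2 to -0.19 at resolution 2.0. These directions depend on the clustering, and the list was not tested again. This class rested on 12 cells in library 2.

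In cluster 11 Gata3, a transcription factor mutated in a syndrome of hypoparathyroidism, deafness and renal disease (chromosome 2, 9857078 to 9890034, minus strand), was higher by a log2 fold change of 7.91 ± 0.28 (1057 ± 340 CPM, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.1e-13). The tight junction claudins Cldn14 (6.80 ± 0.45) and Cldn9 (6.08 ± 0.22, 576 ± 154 CPM), the ATP-gated channel P2rx2 (5.99 ± 0.26), the water channel Aqp4 (8.47 ± 0.39, 164 ± 29.2 CPM) and the transcription factor Isl1 (8.01 ± 0.35, 196 ± 6.13 CPM) were higher. The tectorial membrane protein Ceacam16 differed by 5.17 in library 1 and 7.44 in library 2 (6.36 ± 0.32). Slc26a4, the anion exchanger pendrin (chromosome 12, 31519827 to 31559969, minus strand), had 9 counts in library 1 and 209 in library 2, with differences of 2.31 and 6.78 (7.20 ± 0.93, edgeR adjusted p = 6.1e-04). Of the tested genes 910 were higher and 461 lower, and of 117 deafness genes 43 were higher and 9 lower, with 48 higher when adjusted over the list alone. Of 9 deafness genes of gap and tight junctions 8 were higher (camera, adjusted p = 9.0e-11, and adjusted p = 0.0511 with an estimated correlation). Of 15 of the extracellular matrix 8 were higher, or 9 when adjusted over the list alone (camera, adjusted p = 5.8e-04, and adjusted p = 0.0601 with an estimated correlation). Of 15 transcription factors 8 were higher, or 9 when adjusted over the list alone (camera, adjusted p = 0.0030, and adjusted p = 0.108 with an estimated correlation). Immediate early and heat shock genes were lower in 19 of 26 cases, 20 when adjusted over the list alone (1.2e-14, and adjusted p = 0.0376 with an estimated correlation).

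In non-sensory cochlear epithelium-like cells Lrp2 (megalin, an endocytic receptor, chromosome 2, 69424340 to 69586065, minus strand) was higher by a log2 fold change of 8.18 ± 0.68 (1223 ± 66.2 CPM, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.7e-06), with 8.09 and 6.84 in libraries 1 and 2. The transcription factors Lmx1a (8.00 ± 0.50, with 6.24 and 5.43) and Otx2 (127 ± 18.7 CPM), the secreted peroxidase Gpx3 (3784 ± 664 CPM) and the binding protein of corticotropin releasing hormone, Crhbp (9.94 ± 0.27, 747 ± 135 CPM), were higher. Slc26a4 was higher by 6.79 ± 1.36, with 5.58 and 3.58 per library (134 ± 60.6 CPM, edgeR adjusted p = 0.0105), and Kcnq1, a potassium channel, by 6.13 ± 0.99 on 5 counts in each library. Of the tested genes 630 were higher and 372 lower, and of 117 deafness genes 25 were higher and 9 lower, with 29 higher when adjusted over the list alone. Of 11 deafness genes of ion and metabolite transport 4 were higher (camera, adjusted p = 0.0273, and adjusted p = 0.164 with an estimated correlation). Of 9 of gap and tight junctions 6 were higher, or 7 and 1 lower when adjusted over the list alone (camera, adjusted p = 0.0028, and adjusted p = 0.143 with an estimated correlation). Immediate early and heat shock genes were lower in 19 of 26 cases and higher in 1 (1.1e-20, and adjusted p = 0.0192 with an estimated correlation). The class rested on 16 and 14 cells. With DESeq2 size factors the median of all genes moved from -0.06 to 0.07.

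Macrophage-like cells expressed chemokines and every tested gene of antigen presentation. Ccl12, a monocyte chemokine, was higher by a log2 fold change of 9.46 ± 0.26 (1202 ± 427 CPM, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.5e-31). Il1b (325 ± 115 CPM, with 6.51 and 7.31 in libraries 1 and 2), the complement receptor C3ar1 (277 ± 47.1 CPM) and the hyaluronan receptor Lyve1 (131 ± 15.8 CPM) were higher. The chemokines Ccl3 (chromosome 11, 83647844 to 83649355, minus strand) and Cxcl2 differed more in library 2, with 8.11 and 9.64, and 4.55 and 9.38. Of 14 antigen presentation genes 14 were higher (camera, adjusted p = 4.8e-25, and adjusted p = 0.0151 with an estimated correlation), with H2-Aa by 8.66 ± 0.31, Cd74 by 8.47 ± 0.16 and B2m by 2.78. Of 27 cytokines and chemokines 14 were higher and 4 lower, 15 and 5 when adjusted over the list alone (1.6e-12, and adjusted p = 0.00798 with an estimated correlation). Potassium and chloride handling genes were lower in 5 of 20 cases (0.0371, and adjusted p = 0.303 with an estimated correlation). Among deafness genes the endothelin receptor Ednrb was higher (43.8 ± 5.71 CPM), with 9 of 117 higher and 11 lower in all, and 9 higher when adjusted over the list alone. Of the tested genes 576 were higher and 495 lower, so that 53.8% of the calls were higher, against 65.5% with DESeq2 size factors, which moved the median of all genes from -0.38 to -0.12.

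The erythroid cell-like class joined 4 unlike clusters. The largest (227 cells) had a median of 464 genes and 91.6% haemoglobin, and another (91 cells) had 1867 genes and 51.5%. The sums do not show which of them expressed a gene. The topoisomerase Top2a was higher in the sums by a log2 fold change of 9.29 ± 0.30 (399 ± 59.6 CPM, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.6e-40). The DNA replication helicase subunit Mcm2, a deafness gene (chromosome 6, 88883474 to 88898780, minus strand), was higher by 5.82 ± 0.25 (195 ± 92.2 CPM) and lamin A/C (Lmna) by 2.59 ± 0.19. Rhd, the Rhesus blood group protein, was higher by 10.15 ± 0.26, with 7.97 and 9.11 per library. Of 25 cell cycle genes 25 were higher (camera, adjusted p = 5.7e-29, and adjusted p = 0.0891 with an estimated correlation). The classes compared with left out B lineage-like cells, with Top2a at 769 CPM unscaled in library 1. They also left out cluster 14, whose cell cycle genes were higher in the second fit. High cell cycle genes are therefore not particular to this class. Of 28 antioxidant and glutathione genes 18 were higher and 4 lower (6.6e-06, and adjusted p = 0.269 with an estimated correlation), among them the glutathione peroxidase Gpx1 (5.75 ± 0.15), the glutamate-cysteine ligase subunit Gclm (5.72) and catalase (Cat, 4.13). Oxidative phosphorylation genes were higher in 29 of 50 cases, 30 when adjusted over the list alone (3.5e-05, and adjusted p = 0.604 with an estimated correlation). Immediate early and heat shock genes were lower in 20 of 26 and higher in 4, 21 and 4 when adjusted over the list alone (camera, adjusted p = 2.4e-07, and adjusted p = 0.0601 with an estimated correlation). Of the tested genes 1365 were higher and 1079 lower, with 1021 of the former higher in both libraries, and of 117 deafness genes 24 were higher and 22 lower, with 23 higher when adjusted over the list alone. The 24 fell to 14 with the DESeq2 test, 15 with clustering on all variable genes and 7 with centred genes. Lower genes fell to 410 at a resolution of 2.0. Genes called higher made up 55.9% of the calls, against 46.9% with DESeq2 size factors and 60.7% with haemoglobin genes left out, so the majority depends on the scaling. The median of all genes moved from -0.10 to -0.30 and to 0.02 in the same settings.

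Hair cell-like cells, which had under 10 cells in library 2, entered a second fit of 15 classes with at least 3 cells in each library, a setting added after the cells had been counted. The larger of the 2 clusters in the class (42 cells) had a median of 10.7% mitochondrial UMIs. In a setting with at least 500 genes and at most 10% mitochondrial UMIs, cells were clustered and named again. It held 18 and 1 hair cell-like cells, against 48 and 4 (Jaccard index 0.731 among the cells kept). Part of this fall came from clustering again, not from the filter. The genes were not tested under that filter, so cell quality stays open. Genes of the hair bundle and of the synapse were higher. Lhfpl5 of the mechanotransduction complex (chromosome 17, 28575641 to 28585679, plus strand) was higher by a log2 fold change of 9.43 ± 0.28 (493 ± 135 CPM). The hair cell transcription factor Pou4f3 (chromosome 18, 42394539 to 42397249, plus strand) was higher by 9.40 ± 0.27, and the transduction channel subunit Tmc1 by 7.32 ± 0.46 (97.3 ± 17.3 CPM, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 8.5e-54). Otoferlin (Otof, chromosome 5, 30367062 to 30461932, minus strand), the calcium sensor of the hair cell synapse, had 1587 and 120 counts and 1805 ± 147 CPM. The bundle motor Myo7a stood at 168 ± 118 CPM, and the vesicular glutamate transporter Slc17a8 stood at 1067 ± 45.6 CPM. The neurotrophin Bdnf was higher by 8.26 ± 0.34 (206 ± 10.2 CPM). Of 6068 genes 1282 were higher and 695 lower, 970 of the former in both libraries, and of 140 deafness genes 71 were higher and 13 lower, with 72 higher when adjusted over the list alone. Of 31 deafness genes of the hair bundle 25 were higher and 2 lower (camera, adjusted p = 4.1e-16, and adjusted p = 0.224 with an estimated correlation). Of 9 of the synapse, channel or motor group 8 were higher (camera, adjusted p = 6.9e-09, and adjusted p = 0.140 with an estimated correlation). Of 30 genes near adult hearing difficulty signals 17 were higher and 1 lower, 18 when adjusted over the list alone (4.9e-06, and adjusted p = 0.342 with an estimated correlation). Of 34 deafness genes of mitochondria, translation or other functions 13 were higher and 4 lower, and the list did not pass (camera, limma, adjusted p = 0.229).

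The same fit held clusters 14, 15 and 16. Cluster 15 was higher in the otogelin gene Otog (6.21 ± 0.29, 278 ± 17.7 CPM, with 4.83 and 5.76 in libraries 1 and 2), which encodes a protein of the acellular membranes of the inner ear, and in the tight junction gene Ildr1 (5.23 ± 0.28). Cluster 16 was higher in Gata3 (6.59 ± 0.23), Cldn9 (4.94 ± 0.23) and Aqp4 (7.75 ± 0.28, with 5.45 and 6.64). Cluster 14 was higher in the chemokine Ccl6 (7.89 ± 0.31, with 5.80 and 6.96) and in Cebpe, a transcription factor of granulocyte maturation (9.50 ± 0.34). The numbers of higher and lower genes by edgeR were 866 and 246 in cluster 15, 996 and 294 in cluster 16 and 963 and 714 in cluster 14, with 665 and 911 of the higher ones in clusters 15 and 16 higher in both libraries. Of 140 deafness genes 49, 39 and 10 were higher in the same order, and 52, 40 and 10 when adjusted over the list alone. Without library 1, 501 of the 963 higher genes of cluster 14 and 6 of its 10 deafness genes kept their direction. Deafness genes of gap and tight junctions were higher in 8 of 9 cases in cluster 15 (camera, adjusted p = 1.4e-11, and adjusted p = 0.0788 with an estimated correlation) and in 7 of 9 in cluster 16 (1.1e-05, and adjusted p = 0.174 with an estimated correlation). In cluster 14, 27 of 27 cell cycle genes were higher (2.8e-15, and adjusted p = 0.363 with an estimated correlation) and 12 of 14 antigen presentation genes (2.0e-07, and adjusted p = 0.311 with an estimated correlation). For connexins and pannexins in cluster 15 the median log2 fold change was -1.20 and the mean 0.29, while the test gave a higher list (0.0234, and adjusted p = 0.207 with an estimated correlation). Each of these clusters rested on 4 to 7 cells in library 2.

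In the first fit 69 of 264 tests of a list in a contrast passed with the preset correlation and 7 with an estimated one. The 7 were glycolysis in fibrocyte-like cells, matrix genes in fibroblast-like cells, deafness matrix genes in cluster 8, immediate early and heat shock genes in cluster 11 and in non-sensory epithelium-like cells, and cytokines and chemokines and antigen presentation in macrophage-like cells.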

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

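The tests in this part were chosen after the results had been seen, and the design, with 1 group, gives no biological explanation to test.

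Barcodes with fewer than 300 genes, which no comparison used, were taken up almost wholly by haemoglobin UMIs, at 95.13% in library 1 and 95.974% in library 2. They stand here because this signal lies outside the main measurement and above the limit that a count of 0 allows.

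Haemoglobin UMIs were present in the other classes too, with a median share of 0.626% of a cell's UMIs in library 1 and 0.193% in library 2. Within a library the highest class median was at most 1.422 times the lowest, so free RNA in the droplets may be the source. Free RNA with the makeup of the erythroid cell-like cells is argued against, since the ratio of Hbb-bs to Hba-a1 was at least 2.462 times as high in other cells as in erythroid cell-like cells of the same library (4.34 against 1.76 in library 1 and 3.63 against 1.28 in library 2). In 21 of 921 other cells of library 1 (2.28%, exact interval 1.42% to 3.46%) and 1 of 600 in library 2 haemoglobin exceeded 5%, and in the former the ratio was 1.132 times that of erythroid cell-like cells, which is consistent with red cells captured together with another cell. Whether free RNA was the source, and of which cells, stayed open, since empty droplets were not analysed here.

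The immediate early and heat shock share differed 22.95-fold between the highest and lowest of 15 classes. Part of this came from haemoglobin, which takes most UMIs of erythroid cell-like cells, the lowest class. Haemoglobin as the whole cause is argued against by a 7.171-fold difference that remained among UMIs outside haemoglobin. The classes took a similar order in both libraries, which argues against a pattern that came from 1 library alone. Their Spearman correlation between libraries was 0.925, with a median ratio of library 2 to library 1 of 1.02. Among UMIs outside haemoglobin the values were 0.904 and 1.01. A shift common to all classes of a library could not make its classes differ, so these values do not bear on it. The share and the median depth of a class correlated at 0.304 in library 1 and -0.146 in library 2, too weak and too mixed to decide. Fibroblast-like and non-sensory epithelium-like cells had medians of 5604 and 5818 UMIs in library 1, with shares of 2.52% and 0.570%. In library 2 they had 5517 and 5821 UMIs, with shares of 2.44% and 0.669%. In cluster 6 the medians were 23790 and 6626 UMIs in libraries 1 and 2, and the shares 3.48% and 3.53%. For these classes the values argue against depth as the whole cause, while depth as a part of it stays open. No test separated a response to dissociation from a state of the living tissue, because all cells went through the same dissociation.

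Kcne1 in the cochlear fibrocyte-like class came from library 2 alone, with 190 UMIs against 0 in library 1. Free RNA is argued against by its level, 75.72 times that of all other cells of library 2. Of these UMIs 99.47% lay in the 9 cells with more stria marginal than fibrocyte marker UMIs (50 against 5), so marginal cells grouped into the class are a candidate explanation. These cells also held 97.4% of the Kcnq1 and 90.7% of the Slc12a2 UMIs of the class in library 2, but 0.108% of the Gjb2 UMIs.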

How the results depend on the processing

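The settings with at least 3 cells, centred genes, haemoglobin, the erythroid class left out, the Scrublet rate of 6% and marginal markers were chosen after seeing the data, and the others before. Alternatives that could not change a result are left out of these counts: the Scrublet rate of 6%, which marked the same doublets, and single libraries for shares and for genes named as alike in both. Named genes kept direction and call in 3641 of 3744 alternatives, lost the call in 98 (50 of them under the DESeq2 test) and reversed in 5. Counts of higher genes stayed within 1.5 times in 169 of 172 alternatives, of lower genes in 147 of 172 and of higher deafness genes in 167 of 172, and in the second fit in 52, 53 and 53 of 56. Like counts need not be the same genes. Of the genes higher in the first fit, 49.96% (erythroid cell-like, centred genes) to 100% (macrophage-like, DESeq2 size factors) were called again. With counts within 1.5 times, this was 61.0% in erythroid cell-like cells at resolution 2.0 and 62.9% in fibrocyte-like cells with centred genes. The counts of fibrocyte-like against fibroblast-like cells stayed within 1.5 times in 16 of 16 alternatives per direction, with no value for centred genes. Shares moved by less than the spread between the libraries in 95 of 103. List calls fell from 69 to 7 with an estimated correlation, and numbered 71 with DESeq2 size factors. The median over 15 classes of the correlation between the libraries was 0.8477 on held-out genes alone, against 0.8454. The causes of the changes below were not tested. Low cell numbers limit the rare classes, of which several had 4 to 16 cells in library 2.

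Without the replicate block fewer genes were called lower: 186 against 320 in cluster 4, 104 against 179 in cluster 5, 107 against 181 in cluster 6, 23 against 60 in cluster 8, 87 against 148 in fibroblast-like cells and, in the second fit, 193 against 294 in cluster 16. List calls without the block numbered 78. The library is a shared suspension, so the block pairs the classes of a library by design.

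With at least 20 cells, lower genes numbered 765 against 461 in cluster 11, 530 against 320 in cluster 4 and 266 against 148 in fibroblast-like cells, and higher deafness genes 7 against 13 in cluster 3. With at least 3 cells, lower genes numbered 206 against 461 in cluster 11, 108 against 70 in cluster 3, 305 against 495 in macrophage-like and 194 against 372 in non-sensory epithelium-like cells. The DESeq2 test gave 36 lower genes against 60 in cluster 8, 205 against 495 in macrophage-like and 239 against 372 in non-sensory epithelium-like cells, and 14 higher deafness genes against 24 in erythroid cell-like cells and 25 against 39 in cluster 16. Without doublet removal cluster 3 had 317 higher genes against 492, 35 lower against 70 and 7 higher deafness genes against 13, and macrophage-like cells 325 lower against 495. Clustering on all variable genes gave cluster 3 143 lower genes against 70 and erythroid cell-like cells 15 higher deafness genes against 24. A resolution of 0.5 gave 340 lower genes against 179 in cluster 5 and 96 against 60 in cluster 8, and a resolution of 2.0 gave 410 against 1079 in erythroid cell-like cells.

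With genes centred within each library before clustering, higher genes numbered 595 against 910 in cluster 11, 726 against 1365 in erythroid cell-like cells, 520 against 866 in cluster 15, 531 against 996 in cluster 16 and 814 against 1282 in hair cell-like cells. Lower genes numbered 270 against 461 in cluster 11, 188 against 60 in cluster 8, 608 against 1079 in erythroid cell-like cells, 177 against 372 in non-sensory epithelium-like cells, 125 against 246 in cluster 15 and 159 against 294 in cluster 16, and higher deafness genes 7 against 24 in erythroid cell-like cells and 19 against 39 in cluster 16. The 5 reversals concerned connexins. With centred genes Gjb2 stood at -0.49 in cluster 8 (1.41 before) and -0.49 in cluster 16 (1.30), and Gjb6 at -0.61 in cluster 8 (1.05) and -0.41 in erythroid cell-like cells (1.10). At a resolution of 2.0 Gjb2 in cluster 8 stood at -0.19.

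Mean shares moved to 6.11% from 3.90% in cluster 11 and to 6.40% from 6.67% in cluster 5 at a resolution of 0.5, and to 5.61% from 6.74% in cluster 4 at 2.0. Without doublet removal they moved to 7.68% in cluster 4 and 6.99% in cluster 5, with the stricter cell filter to 7.82% in cluster 5 and 2.31% from 4.39% in fibrocyte-like cells, and with centred genes to 5.68% from 19.1% in fibroblast-like cells, of which 151 and 0 cells remained while another cluster held 4 and 167. The stricter filter, with cells clustered and named again, also took hair cell-like cells from 48 and 4 to 18 and 1. Their mean share went from 2.12% to 0.856%, which the wide spread between the libraries covers.

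Leaving out each library in turn, counted as called genes that kept their direction, gave ranges of 501 to 963 higher genes and 6 to 10 higher deafness genes in cluster 14, the lower values without library 1. In every other class and in both directions these counts stayed within 1.5 times of the full ones. The counts above leave out classes with too few cells and units without a match: clusters 3, 4, 5 and 6 with centred genes, 3, 4, 6 and 16 at a resolution of 0.5, 4 and 5 on all variable genes, and spiral ganglion neuron-like cells with the stricter filter.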

Other observations

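Classes that came from a single library are given as values without a test, in CPM of that class without TMM factors, with exact Poisson 95% intervals that cover counting error only. Stria intermediate cell-like cells, the pigment cells that generate the endocochlear potential, stood at 1643 CPM for the potassium channel Kcnj10 in library 2 (19 cells, 1384 to 1937), at a log2 ratio of 6.30 to the rest of the library. They held 1227 CPM of the endothelin receptor Ednrb, 220 of the transcription factor Pax3, 440 of Sox10, 1910 of Gjb6 and 6910 of the sodium pump subunit Atp1b1. Ednrb, Pax3, Sox10 and Mitf (266 CPM, 169 to 399) are known from Waardenburg syndromes and related conditions of pigment loss with deafness.

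Organ of Corti supporting cell-like cells of library 1 (27 cells) held 7167 CPM of the tectorial membrane gene Ceacam16 (6912 to 7429), 500 of the tight junction gene Ildr1, 992 of the cytoskeletal gene Gas2 and 413 of Otog. Spiral ganglion neuron-like cells of library 1 (6 cells) held 2726 CPM of complexin 1, Cplx1 (2515 to 2951), 1243 of synaptophysin, Syp, and 441 of the calcium pump Atp2b2. B lineage-like cells of library 1 (70 cells) held 769 CPM of Top2a (706 to 836) and 5104 of the chromatin protein Hmgb2, genes of cell division, and 228 of the antigen presentation gene H2-Ab1, against 42.9, 373 and 14.2 CPM in the rest of the library.

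Of 4 genes of the Y chromosome 0 UMIs were counted in both libraries, against 6782 UMIs of their 4 X homologues, which allows at most 0.0442% of the latter. Xist, expressed from the inactive X chromosome, was seen in 1033 of 1329 cells of library 1 (77.7%) and 585 of 639 of library 2 (91.6%), and in 95.4% and 95.5% of the cells outside the erythroid class. The labels do not give the sex of the mice.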
